A study of Xenopus laevis with 9 samples.

How the data were processed

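RNA from tadpole tails of the frog Xenopus laevis was hybridised to 9 Affymetrix Xenopus laevis arrays, short-oligonucleotide arrays on which each transcript is read by a set of probes. Per the labels, the tadpoles were at stage 54 and were kept as 2 larvae per 500 ml container at 20 C in a buffered amphibian medium (FETAX). They were exposed to vehicle for 48 h, to 20 nM of the thyroid hormone 3,5,3'-triiodothyronine (T3) for 6 h or to 20 nM T3 for 48 h. Each group had 3 arrays, and each array was made from the RNA of a pool of 3 tails. The pools were separate samples per the labels. Nothing in the sources used here says whether the pools of a group came from separate clutches or exposure runs, so the p-values measure the spread between these pools. Vehicle tails were taken at 48 h only, so T3 6 h and vehicle differ in hormone and also in time in the container.

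The deposited values are intensities on a linear scale, 1 per probe set and array. They were made with GCRMA, which corrects probe intensities for background from probe sequence and summarises each probe set, per the submitters' processing notes. The GCRMA version, and any other step, is not given in the sources used here. In the deposited table each of the 9 columns has a median of 1, so each array had been divided by its own median, and the values were not centred per probe set. The log2 of each deposited intensity was taken before any other step, so a log2 value of 0 is the median of its array. The files hold no detection calls. For a probe set below the array median in a group, the fold change therefore depends on the background correction, and such folds are less certain than those of brighter probe sets. No scan dates or batches are given in the sources used here. As for other arrays, precision is limited by the number of arrays.

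The table held 15611 probe sets, of which 120 control probe sets were left out of the tests. The design fixed before the data were examined had a level filter of log2 4 in at least 3 of the 9 arrays, which assumed an absolute log2 scale. On values divided by the array median that level is far above the median and would keep 1474 probe sets. Before any test was run, the filter was set to log2 0, the array median, in at least 3 of the 9 arrays, which kept 8123 of 15491 probe sets. The filter as first written was added as an alternative after the scale of the values had been seen. Gene symbols came from the platform annotation. Of the 15491 probe sets, 9304 had 1 gene, 195 had several and 5992 had none listed. By gene ID, 9227 probe sets matched a RefSeq gene table of the assembly Xenopus_laevis_v10.1, which was used for names only and updated 2 symbols. Probe sets with several genes or none were tested and counted but not named, among them a probe set that matches the thyroid hormone receptor thrb together with other genes. Xenopus laevis carries most genes as a pair of homeologs, written .L and .S, and a probe set designed for 1 of them can also bind the other, so values of close homeologs are uncertain. Genomic positions of the probe sets were not used here.

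The log2 values of all 9 arrays were fitted together with limma 3.58.1 in R 4.3.3, with group as the only factor, so that the 3 groups shared an estimate of the spread. Moderated statistics came from eBayes with an intensity trend. All tests were two-sided. A probe set was called when its Benjamini-Hochberg adjusted p was under 0.05, without a fold minimum. The comparisons were T3 6 h against vehicle, T3 48 h against vehicle, and T3 48 h against T3 6 h, and the last is also the difference between both effects against the shared vehicle arrays. Tails of T3 48 h and T3 6 h differ in time in the container as well as in T3, which these arrays do not separate. Errors beside fold changes are standard errors (SE) of the fit, and errors beside group means are SD over 3 arrays. The procedure was tested on 20 simulated data sets for T3 48 h against vehicle with 8123 probe sets, of which 200 were changed. It recovered 78.1% of changes of log2 1 and 97% of changes of log2 2, with 4.82% false calls on average. In the list test, run on 4719 genes, a shift of log2 0.5 was found in 20 of 20 runs, with a mean of 0.1 false list calls per run. The simulated genes varied independently, so these runs do not test how correlation between genes affects the list test.

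The 27 gene lists, fixed before the data were examined, were T3 response genes, thyroid hormone transport and metabolism, nuclear receptor coregulators, matrix-degrading enzymes (with their inhibitors), extracellular matrix, apoptosis, lysosome and autophagy, proteasome, muscle, myogenic regulators, epidermis, cell cycle and DNA replication, glycolysis, oxidative phosphorylation, ribosomal proteins, endoplasmic reticulum (ER) stress and chaperones, erythroid, leukocytes, neural, notochord and cartilage, vascular endothelium, pigment cells, signalling of growth and patterning, corticosteroid axis, immediate early genes, circadian clock, and liver, pancreas and gut. Homeologs counted as separate members. The lists were tested with camera in limma at a preset correlation of 0.01 between genes, on the brightest probe set per gene among 4719 genes, with adjustment over the 81 list tests. No list was called when camera estimated the correlation from the data. The adjusted p of that version stands beside each list call. Fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, was another alternative. Counts of called members are given over all probe sets tested and adjusted over the list alone.

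Genes were named by a rule fixed beforehand. It named every measured member of the T3 response list whatever its result, those below the filter being tested in a fit of all 15491 probe sets. It named, for each comparison, the 10 largest rises and the 10 largest falls among called probe sets with a single informative symbol whose groups of 3 arrays did not overlap, with 1 probe set per gene, and fewer where fewer passed. It also named up to 4 called members of each list. By chance 10% of probe sets have groups of 3 that do not overlap. Genes named outside this rule are said to have been chosen after their values were seen.

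Alternatives were no filter, filters at log2 6 and as first written, quantile normalization, centring on the tested probe sets, the replicate number as a block, other variance models, array weights, a fit of only the groups compared, stricter thresholds, removal of probe sets that can match several transcripts, and each array left out in turn. For the gene lists, the filter at log2 6, centring and the counts without T3 48 h array 1 or T3 6 h array 2 were added after the data had been seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.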

Results

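Gene expression was measured in the tails of stage 54 Xenopus laevis tadpoles, larvae with a large muscular tail that is later resorbed at metamorphosis under thyroid hormone. The series compared tails after 48 h in vehicle with tails after 6 h and 48 h in 20 nM T3, the active thyroid hormone, at a stage chosen by the submitters because the larvae have little hormone of their own but can respond to it. Each group held 3 arrays, each from a pool of 3 tails, and 8123 probe sets were tested. Array intensities carry no read depth, and the number of arrays limits the precision. Values of arrays within a group correlated across probe sets at r = 0.966 to 0.988. The first principal component took 47.2% of the variance. It separated the T3 48 h arrays, at scores of 15.2, 38.8 and 30.7, from the vehicle and T3 6 h arrays, which lay between -16.6 and -11.3. T3 48 h array 1, at 15.2, stood apart from the other T3 48 h arrays on the side of the vehicle arrays. On the second component, T3 6 h array 2 lay at -3.51 and T3 6 h arrays 1 and 3 at -19.3 and -17.4.

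**Figure D1:**
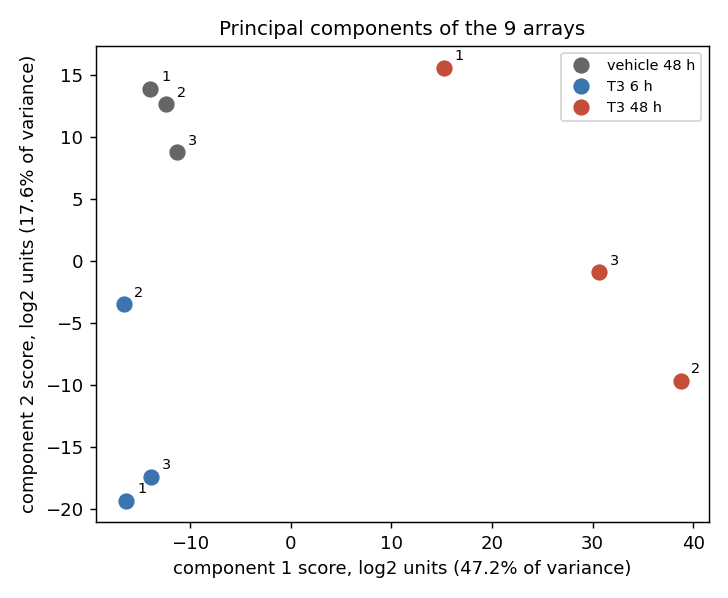
Scores of the 9 arrays on the first (x axis, 47.2% of variance) and second (y axis, 17.6%) principal components of the tested probe sets, in log2 units, with each point an array coloured by group and numbered by replicate. The T3 48 h arrays lie to the right at 15.2 to 38.8, with array 1 nearest to the others.

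The first comparison asked which transcripts respond within 6 h. The largest rises at 6 h were in gclm.L, the regulatory subunit of the enzyme that limits glutathione synthesis, at 3.62-fold (log2 1.85 ± 0.26 SE, n = 3, adjusted p = 0.0432 in limma), and in the parvalbumin family gene ocm4.3.S (log2 1.76 ± 0.26). A further rise was in sqstm1.L, the autophagy receptor p62, at 2.48-fold (log2 1.31 ± 0.13, adjusted p = 0.0103). The muscle-determining transcription factor myod1.S fell 2.61-fold (log2 -1.38 ± 0.19), from 3.22 ± 0.35 in vehicle to 1.84 ± 0.18 (SD, n = 3, log2 over the array median). The secreted Wnt antagonist sfrp2.S fell 2.48-fold (log2 -1.31 ± 0.21), both genes at an adjusted p of 0.0432. In all, 18 probe sets were called in limma, 14 higher and 4 lower, of which 7 changed at least 2-fold, and 1270 had an unadjusted p under 0.05. The count was 0 with the replicate number as a block, 1, higher, under quantile normalization, 2 without a filter and 547, 321 higher and 226 lower, with array weights. The other named rises were eef1aknmt.S (log2 0.99), grina.L (0.99), lgals4.2.L (0.83), mrto4.L (0.73) and arpp19.L (0.67), and the other falls were lmbr1l.L (-0.82) and tmem52.L (-0.75). The other 6 called probe sets, all higher, carry no gene name here. Of the fits without 1 array, the count was 0 without vehicle array 1, vehicle array 2 or T3 6 h array 1, 7 without vehicle array 3 and 1 without T3 6 h array 3. Without T3 6 h array 2 it was 22, of which 8 were among the 18. It was 99, 3 and 1 without T3 48 h arrays 1, 2 and 3, and none of the 12 named genes kept its call in all 9 of these fits.

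At 6 h, the T3 response list, which holds hormone receptors and genes known to answer T3 in tadpoles, had 0 of 6 tested members called (1 higher when adjusted over the list alone), with a median log2 change of 0.11 and an adjusted p of 0.52 for the list. Its largest value was that of dio3.L, the deiodinase that inactivates thyroid hormone, at log2 1.27 ± 0.27 (adjusted p = 0.0861), from 1.63 ± 0.29 in vehicle to 2.90 ± 0.31 (SD, n = 3). The matrix-related genes fap.L and mmp11.L were at 0.31 ± 0.26 and -0.12 ± 0.25. Further values were 0.15 for prmt1.S, -0.25 and 0.07 for the probe sets of prmt1.L, and -0.33 for fzd2.S. Among members below the level filter, the transcription factor klf9.L was at 0.50 ± 0.21 (adjusted p = 0.425), the receptor thra.L at 0.20, thibz.L at 0.14, thibz.S at 0.24, crhbp.S at -0.13, nfix.L at -0.41, dio2.L at 0.10 and 0.05, mycl.L at 0.18, mycl.S at 0.04 and -0.34, and klf9-b at 0.07, none of them called.

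At 6 h the lists of growth signalling, matrix and myogenic regulators were called lower and those of the proteasome and chaperones higher, with 1, 0, 1, 0 and 0 members called. The extracellular matrix list fell, with a median of -0.32 over 26 members (adjusted p = 1.61e-05 in camera, and 0.489 with an estimated correlation). None of them was called over all probe sets, and 1 was higher and 3 lower when adjusted over the list alone. Signalling of growth and patterning fell, with a median of -0.28 over 29 members (adjusted p = 4.03e-05, and 0.373 with an estimated correlation). sfrp2.S was called, and 4 were lower when adjusted over the list alone. The myogenic regulators fell, with a median of -0.23 over 9 members (adjusted p = 0.0015, and 0.373 with an estimated correlation). myod1.S was called, and 3 were lower when adjusted over the list alone. The proteasome list rose, with 41 of 47 members positive and a median of 0.19 (adjusted p = 0.000526, and 0.693 with an estimated correlation). ER stress and chaperones rose, with 44 of 55 positive and a median of 0.17 (adjusted p = 0.00264, and 0.614 with an estimated correlation). Neither list had a member called over all probe sets, and adjusted over the list alone 1 proteasome member was higher and 0 chaperone genes changed. Smaller falls were called for ribosomal proteins (median -0.03 over 69 members, adjusted p = 0.00822, and 0.693 with an estimated correlation), cell cycle and DNA replication (-0.11 over 33, adjusted p = 0.014, and 0.685 with an estimated correlation) and immediate early genes (-0.17 over 20, adjusted p = 0.0338, and 0.693 with an estimated correlation). None of their members was called over all probe sets, and 1 immediate early gene was higher when adjusted over the list alone. Without vehicle array 2 the proteasome list came to an adjusted p of 0.051, the cell cycle list to 0.278 and the immediate early list to 0.647. The immediate early list also lost its call under centring (0.0518) and without T3 6 h array 1 (0.0554) or array 2 (0.18), as the ribosomal list did without T3 6 h array 1 (0.181). Counts without T3 48 h array 1, a setting added after the data had been seen, were 2 higher for the proteasome, 1 higher each for T3 response genes, thyroid hormone transport and metabolism, lysosome and autophagy, erythroid, leukocytes and immediate early genes, 3 lower for growth signalling and 1 lower each for extracellular matrix and myogenic regulators, with 0 in the other lists. Without T3 6 h array 2, also added, they were 1 higher each for lysosome and autophagy and erythroid and 0 in the other lists, with myod1.S and sfrp2.S at an adjusted p of 0.0503 and 0.0570. The ribosomal median of -0.03 was -0.06 under centring.

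No list of another cell type was called at 6 h, and no member of one, although 1 erythroid and 1 leukocyte member were higher without T3 48 h array 1, and 1 erythroid member without T3 6 h array 2. The erythroid list had a median of 0.31 over 10 members (adjusted p = 0.292), with 0 called over all probe sets and 3 higher when adjusted over the list alone. Of the 10, 6 were positive and 4 negative. Its globins had positive values, hba4.S at 1.46, hbg2.L at 1.44, hba3.L at 1.07 (adjusted p = 0.0588), hba2.L at 0.93 and hbd.S at 0.62, all chosen after their values were seen. These globin values stood beside the falls of the matrix, growth signalling and myogenic lists. The muscle list of 50 contractile and calcium-handling genes had a median of 0.02 (adjusted p = 0.897), which became -0.01 under quantile normalization and under centring. The circadian clock list was at -0.21 over 5 members (adjusted p = 0.518). The adjusted p of the remaining lists was 0.104 for epidermis (median 0.20, 2 of 31 higher when adjusted over the list alone), 0.208 for the corticosteroid axis, 0.319 for neural, 0.389 for vascular endothelium, 0.389 for thyroid hormone transport and metabolism, and 0.407 for nuclear receptor coregulators. It was 0.519 for lysosome and autophagy (sqstm1.L higher), 0.565 for liver, pancreas and gut, 0.725 for oxidative phosphorylation, 0.773 for notochord and cartilage, 0.779 for leukocytes, 0.788 for matrix-degrading enzymes, 0.891 for glycolysis, 0.895 for pigment cells and 0.988 for apoptosis. In the uncalled lists of matrix-degrading enzymes, apoptosis, muscle, oxidative phosphorylation, leukocytes, pigment cells and notochord and cartilage, the median, the mean and the direction of the test did not all have the same sign.

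The second comparison asked what 48 h of T3 changed. Of the tested members, 9 of 16 on the list of matrix-degrading enzymes and their inhibitors (7 proteases and 2 inhibitors) and 3 of 6 T3 response genes rose, and 9 of 31 epidermal and 4 of 5 notochord and cartilage genes fell. fap.L and mmp11.L count on both the matrix-degrading and the T3 response list. The membrane serine protease fap.L rose 28.8-fold, from 0.78 ± 0.06 in vehicle to 5.63 ± 0.59 after 48 h (SD, n = 3; log2 4.85 ± 0.26 SE, adjusted p = 1.23e-05 in limma). The collagenase mmp13l.S rose 26.9-fold (log2 4.75 ± 0.40), and mamdc2.L, a secreted proteoglycan, rose 31.2-fold (log2 4.96 ± 0.43). The keratin krt12.4.L fell 8.88-fold (log2 -3.15 ± 0.32, adjusted p = 0.000786), and the cartilage collagen col2a1.S fell 3.39-fold (log2 -1.76 ± 0.41, adjusted p = 0.0272). The T3 48 h values of krt12.4.L, -1.87, -2.00 and -1.80, lay below the array median, so its fold depends on the background correction. In all, 892 probe sets were called, 401 higher and 491 lower, in 554 named genes. The split was 429 higher and 436 lower under quantile normalization and 480 and 410 under centring. Of the 892, 270 changed at least 2-fold, 123 higher and 147 lower. The count was 256 without vehicle array 1, 305 without vehicle array 2, 376 without vehicle array 3, 291 without T3 48 h array 2, 285 without array 3 and 1912 without array 1. In all 9 fits 28 of 73 named results kept their call, among them fap.L, mmp13l.S, mamdc2.L and krt12.4.L but not col2a1.S, which was at an adjusted p of 0.0873, 0.0825 and 0.0504 without vehicle arrays 1, 2 and 3 and at 0.0847 and 0.0885 without T3 48 h arrays 2 and 3.

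**Figure D2:**
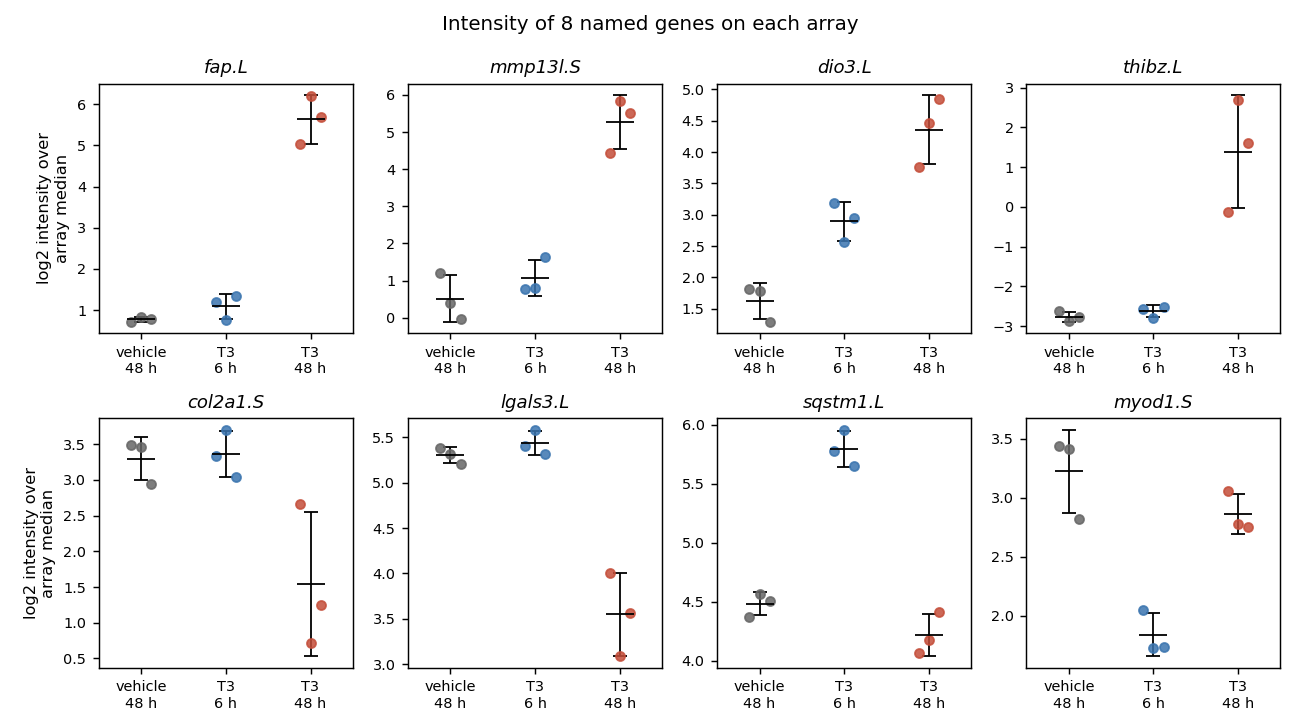
Log2 intensity over the array median (y axis) of 8 named genes in vehicle, T3 6 h and T3 48 h tails, with each point an array, the long bar the mean of 3 arrays and the whiskers its SD. fap.L, mmp13l.S and thibz.L lie higher at 48 h, sqstm1.L is highest and myod1.S lowest at 6 h, and col2a1.S and lgals3.L are lowest at 48 h.

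Of the 6 tested T3 response genes, 3 rose at 48 h, also when adjusted over the list alone, and the list rose (median 1.40, adjusted p = 0.000345, and 0.373 with an estimated correlation). These were fap.L, dio3.L at 6.64-fold (log2 2.73 ± 0.27, adjusted p = 0.000748), and the stromelysin mmp11.L at 5.20-fold (log2 2.38 ± 0.25), each known before these data as T3 responsive. The values of fzd2.S (0.43), prmt1.S (0.15) and prmt1.L (-0.21 and -0.31) did not pass. In the fit of all probe sets, members below the level filter that rose were the leucine zipper factor gene thibz.L (log2 4.15 ± 0.54, adjusted p = 0.00558) and its homeolog thibz.S (1.46 ± 0.21, adjusted p = 0.00781), and the corticotropin-releasing hormone binding protein crhbp.S (3.79 ± 0.72, adjusted p = 0.0237). Also higher in that fit were nfix.L (1.88 ± 0.41, adjusted p = 0.0377) and the activating deiodinase dio2.L (1.82 ± 0.34, adjusted p = 0.0224, with another probe set at -0.02), and mycl.S fell (-0.84 ± 0.18, adjusted p = 0.0335, with another probe set at -0.02). Vehicle values of thibz.L lay at -2.76 ± 0.13 (SD, n = 3), below the array median, so its fold depends on the background correction. Also below the filter, thra.L (0.21 ± 0.13), klf9.L (0.44 ± 0.21), klf9-b (-0.03) and mycl.L (0.04) were not called. The calls of nfix.L, dio2.L and mycl.S were lost without vehicle array 1 (adjusted p = 0.140, 0.0840 and 0.0988), 2 (0.0556, 0.0804 and 0.113) or 3 (0.109, 0.0736 and 0.0834) and without T3 48 h array 3 (0.0755, 0.0763 and 0.0933). That of nfix.L was also lost without T3 6 h array 1, 2 or 3 (0.0570, 0.0537 and 0.0621), and that of mycl.S without T3 6 h array 1 (0.0518). Leaving out T3 48 h array 1 or 2 gave 4.91 and 3.50 for thibz.L, and 4.87 and 3.19 for crhbp.S, whose call was lost without array 2 (adjusted p = 0.0544), array 3 (0.0809) or vehicle array 1, 2 or 3 (0.0908, 0.0798 and 0.0763). Thyroid hormone transport and metabolism also rose (median 0.60 over 5 members, adjusted p = 0.00281, and 0.422 with an estimated correlation). dio3.L, which is also on the T3 response list, and the T3-binding protein crym.S (log2 1.31 ± 0.23) were called and 4 were higher when adjusted over the list alone. In both of these lists 3 members were higher without T3 48 h array 1, an added setting.

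Of 16 matrix-degrading enzymes and inhibitors, 9 rose and 1 fell (10 and 2 when adjusted over the list alone), and the list rose with a median of 0.88 (adjusted p = 2.66e-06, and 0.373 with an estimated correlation). Beside fap.L and mmp13l.S, the dipeptidyl peptidase dpp4.S rose by log2 2.79, mmp13l.L by 2.42, mmp11.L by 2.38, the membrane collagenase mmp14.L by 1.05 and the gelatinase mmp2.S by 0.71. On all 3 vehicle arrays dpp4.S lay below the array median. The metalloproteinase inhibitors timp2.S and timp2.L rose by 1.70 and 1.23, and mmp28.L fell (-0.52). Matrix genes themselves went both ways, with 2 of 26 members of the extracellular matrix list higher and 6 lower (3 and 7 when adjusted over the list alone). Its median was 0.00 and its adjusted p 0.788, the direction of the test being opposite to the mean of -0.16. The proteoglycan bgn.L rose (log2 1.77 ± 0.19), as did the collagen-modifying p4hb.L (0.45), whereas col9a1.L (-1.86), col2a1.S (-1.76), col9a1-b (-1.54), tnc.L (-0.95), vcan.L (-0.69) and col18a1.S (-0.58) fell. Of 5 notochord and cartilage members, 4 fell over all probe sets and when adjusted over the list alone, these 3 cartilage collagen probe sets and cnmd.L, the cartilage protein chondromodulin (-1.28). The list fell with a median of -1.54 (adjusted p = 0.00746, and 0.614 with an estimated correlation). None of these 4 members kept its call in all 9 fits without 1 array, and neither did p4hb.L. The counts without T3 48 h array 1 were 10 higher and 1 lower for matrix-degrading enzymes, 3 and 7 for extracellular matrix and 0 and 4 for notochord and cartilage, and col9a1.L was then at -2.49. Without T3 6 h array 2 the extracellular matrix list had 3 higher and 4 lower. Here mmp13l.L, mmp14.L, mmp2.S, both timp2 homeologs, mmp28.L, tnc.L, vcan.L and col18a1.S were chosen after their values were seen.

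The lists of lysosome and autophagy and of ER stress and chaperones were called higher at 48 h. In lysosome and autophagy 11 of 43 members rose and 0 fell (17 and 2 when adjusted over the list alone; median 0.35, adjusted p = 4.59e-05, and 0.685 with an estimated correlation). The lysosomal galactosidase glb1.L rose 4.63-fold (log2 2.21 ± 0.22), atg16l1.L rose by log2 1.92 ± 0.28, although 3 other probe sets of that gene were not called. The autophagosome protein gabarapl1.S rose by 0.93 and the cathepsins ctsb.L and ctsb.S by 0.77 and 0.58. The protease lgmn.L rose by 0.58, although its probe set shares a cluster number with 1 of the actin gene actg1.L. In ER stress and chaperones 7 of 55 members rose and 0 fell (12 and 0 when adjusted over the list alone; median 0.22, adjusted p = 4.59e-05, and 0.469 with an estimated correlation). They were the folding chaperones hsp90b1.L (log2 1.13), calr.L (0.88) and canx.L (0.85), manf.S (1.07), and the disulfide isomerases pdia6.S (0.65), pdia4.L (0.54) and p4hb.L (0.45). Leaving out T3 48 h array 1 gave 19 lysosomal members higher and 1 lower, and 17 ER members higher and 2 lower. Without T3 6 h array 2 the lysosomal members higher were 7. The values of both cathepsins, actg1.L, manf.S, pdia6.S and pdia4.L at 48 h were chosen after they were seen. Of the other genes named in this paragraph, only glb1.L, atg16l1.L and calr.L kept their call in all 9 fits without 1 array.

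The epidermis list was called lower at 48 h. Of its 31 members 0 rose and 9 fell (1 and 11 when adjusted over the list alone), 6 were positive, and the list fell with a median of -0.35 (adjusted p = 0.000571, and 0.469 with an estimated correlation). The larval keratins krt12.4.L (log2 -3.15), krt12.4.S (-2.38) and krt12.5.S (-1.10), the lectin lgals3.L (-1.75 ± 0.20) and the desmosomal plakophilin pkp3.S (-1.16) were among them. Outside the list the keratins krt12.2.L (-2.24) and krt12.2.S (-2.01) fell too, but neither kept its call in all 9 fits without 1 array. Another keratin, krt78.6.L, rose 11.4-fold (3.51 ± 0.39), from -1.97 ± 0.35, below the array median, to 1.55 ± 0.85 (SD, n = 3). Of the epidermis members, 1 rose and 12 fell without T3 48 h array 1. Among the largest falls were also thdl17.L (log2 -3.28 ± 0.68) and thdl18.S (-3.07 ± 0.69), genes named for being down-regulated by thyroid hormone in larvae. Without T3 48 h array 1 these were at -4.32 and -4.12. Their calls were lost without vehicle array 1, 2 or 3 (adjusted p = 0.0625, 0.0525 and 0.0515 for thdl17.L, 0.0738, 0.0622 and 0.0695 for thdl18.S) and without T3 48 h array 2 or 3 (0.0644 and 0.0655, and 0.0874 and 0.0842). Others were fucolectin.S (-2.49), the proton pump gene atp12a.L (-2.41), otogl2.L (-2.33, with another probe set at 0.06) and the transcription factor klf2.S (-2.16, and -1.51 without vehicle array 2), whose call was lost without T3 48 h array 2 (0.0644) or 3 (0.0715). Nor did atp12a.L keep its call in all 9 fits without 1 array. Among the largest rises were the peptide transporter slc15a2.L (log2 4.23 ± 0.27), ambp.L (3.97 ± 0.81, although 2 other probe sets were at -0.21 and -0.16), the aminopeptidase anpep.L (3.43) and the annexin anxa1.3.S (3.32). The vehicle values of slc15a2.L, ambp.L and anpep.L lay below the array median on all 3 arrays. So did the T3 48 h values of krt12.4.L, krt12.4.S and atp12a.L, and the folds of these genes depend on the background correction. The T3 48 h arrays had ambp.L at 5.25, 0.89 and 2.60. Its change was 2.80 without array 1 and 4.98 without array 2, and its call was lost without vehicle array 1 (adjusted p = 0.0549), vehicle array 2 (0.0586) or T3 48 h array 3 (0.0503).

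The lists of oxidative phosphorylation, ribosomal proteins and the cell cycle were called lower at 48 h, with 3 of 78, 0 of 69 and 3 of 33 members called. Of 78 members of the oxidative phosphorylation list 73 were negative, with a median of -0.22 that became -0.15 under quantile normalization and -0.20 under centring (adjusted p = 8.83e-06, and 0.693 with an estimated correlation). Of these 3 were called, complex I subunits ndufs4.S (log2 -0.43), ndufb5.L (-0.41) and ndufa8.L (-0.33), and 0 when adjusted over the list alone. None of the 3 kept its call in all 9 fits without 1 array. Without T3 48 h array 1 the counts were 1 higher and 17 lower. The epidermis list fell beside it, whereas the muscle list had a median of 0.01. Ribosomal proteins had a median of -0.08 over 69 members, and -0.02 under quantile normalization and -0.05 under centring, with 0 called (adjusted p = 0.014, and 0.693 with an estimated correlation), a call that was lost under quantile normalization (0.741), under centring (0.114, a setting added for the lists after the data had been seen) and without T3 48 h array 2 (0.289). In cell cycle and DNA replication 3 of 33 fell (7 when adjusted over the list alone), the condensin subunits smc4.L (-0.89) and smc2.L (-0.62) and the spindle factor tpx2.S (-0.51). The list fell with a median of -0.22 (adjusted p = 0.0336, and 0.693 with an estimated correlation). It lost its call without vehicle array 2 (0.278) or T3 48 h array 2 (0.0911). In the cell cycle list 1 member was higher and 8 were lower without T3 48 h array 1. smc4.L, smc2.L and tpx2.S did not keep their calls in all 9 fits without 1 array.

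Genes of muscle, the bulk tissue of the tail, had 0 of 50 members called at 48 h, also when adjusted over the list alone, with a median of 0.01 (adjusted p = 0.761). Without T3 48 h array 1, 1 rose and 3 fell. Of 19 neural genes gap43.S rose (log2 1.41 ± 0.18) and stmn1.L (-1.59 ± 0.26), syt1.L (-1.08) and tubb3.L (-0.86) fell, with an adjusted p of 0.389 for the list. Nuclear receptor coregulators had 3 of 11 higher, the coactivator ncoa3.S (0.81), the corepressor ncor1.S (0.77) and the deacetylase hdac1.S (0.58), at a list adjusted p of 0.0812. In leukocytes the chemokine receptor cxcr4.L (0.77) and the factor cebpd.S (0.65) rose (list adjusted p = 0.271), and in vascular endothelium egfl7.S rose (0.64; list 0.199). Immediate early genes had klf6.L (0.70) and cebpd.S higher and 3 members lower, klf2.S and both myc homeologs, myc.S (-0.98) and myc.L (-0.63), at a list adjusted p of 0.787. In growth signalling the receptor tgfbr1.S rose (0.77) and sfrp2.S fell (-0.98), at a list adjusted p of 0.773, where the test direction was opposite to the mean. In glycolysis hk1.L (-1.25) and pfkfb3.S (-1.23) fell and pfkp.S rose (0.54), at 0.349. Other lists had few calls, namely bnip3.S (0.60) in apoptosis (list 0.988), rab27a.L (-0.87) in pigment cells (0.285), sgk1.L (0.84) in the corticosteroid axis (0.782), and arg1.L (1.71) in liver, pancreas and gut (0.86). The proteasome had psmd10.L (-0.85) and psmb9.S (-0.73) lower (0.104), and there was none among erythroid genes (0.285), myogenic regulators (0.518) and the circadian clock (0.133). Without T3 48 h array 1 the members higher and lower were 4 and 0 for coregulators, 2 and 1 for leukocytes, 2 and 4 for neural, 2 and 4 for immediate early genes, 3 and 3 for growth signalling and 1 and 5 for glycolysis. They were 2 and 1 for pigment cells, 1 and 2 for the corticosteroid axis, liver, pancreas and gut, and the proteasome, and 0 and 2 for the circadian clock and for ribosomal proteins. myc.L was chosen after its value was seen. Of the other genes named in this paragraph, sgk1.L among them, only gap43.S, stmn1.L, rab27a.L and arg1.L kept their call in all 9 fits without 1 array.

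**Figure D3:**
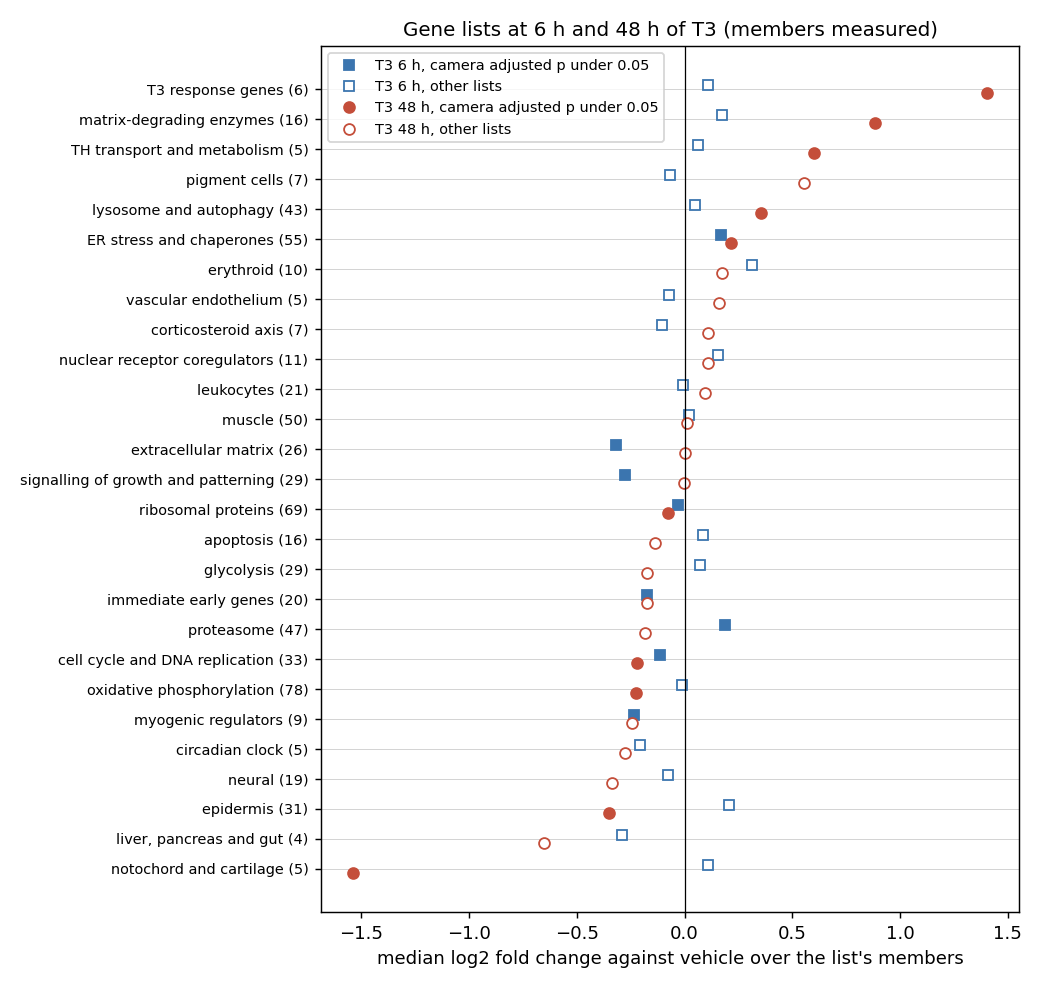
Median log2 fold change against vehicle (x axis) of the 27 gene lists (y axis, with the number of members) after 6 h (squares) and 48 h (circles) of T3, filled where the adjusted p of camera at its preset correlation was under 0.05. The T3 response list lies at 0.11 and 1.40, and the notochord and cartilage list at 0.11 and -1.54; no list was called with an estimated correlation.

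The third comparison set T3 48 h against T3 6 h. These groups differ in the duration of T3 and also in time in the container, and both effects are measured against vehicle of 48 h, so the comparison does not separate hormone from time. Of the tested members, 9 of 16 on the list of matrix-degrading enzymes and their inhibitors (7 proteases and 2 inhibitors) and 3 of 6 T3 response genes were higher at 48 h than at 6 h, and 15 of 31 epidermis, 10 of 47 proteasome and 13 of 78 oxidative phosphorylation members were lower. As above, fap.L and mmp11.L count on both of the lists that were higher. mamdc2.L was 46.9-fold higher (log2 5.55 ± 0.43, adjusted p = 0.000208 in limma), fap.L 23.3-fold (4.54 ± 0.26) and dio3.L 2.76-fold (1.46 ± 0.27, adjusted p = 0.00607), and krt12.4.S was 11.1-fold lower (-3.47 ± 0.38, adjusted p = 0.000633). At 6 h mamdc2.L, and at 48 h krt12.4.S, lay below the array median on every array, so both folds depend on the background correction. Of genes called at 6 h, sqstm1.L was at log2 -1.58 ± 0.13 (adjusted p = 0.000229), gclm.L at -1.33 and myod1.S at 1.02 ± 0.19 (adjusted p = 0.00579). These genes were picked on the T3 6 h arrays that this comparison also uses, which by itself favours the opposite sign. In all, 1578 of the 8123 tested probe sets (19.4%) were called, 610 higher and 968 lower. The counts of list members are to be read beside these. The share of higher calls, 38.7%, became 47.5% under quantile normalization and 50.2% under centring. The count was 869 without T3 6 h array 1, 880 without T3 6 h array 3, 992 without T3 48 h array 3 and 2093 without T3 48 h array 1. Of 80 named results, 55 kept their call in all 9 fits.

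Of the 16 matrix-degrading enzymes and inhibitors 9 were higher and 1, the inhibitor timp3.L (log2 -0.74, chosen after its value was seen), was lower at 48 h than at 6 h (9 and 2 when adjusted over the list alone). The list median was 1.45 (adjusted p = 8.83e-06, and 0.378 with an estimated correlation), with timp2.L at log2 1.76 and mmp11.L at 2.50. T3 response genes had 3 of 6 higher (4 when adjusted over the list alone; median 1.11, adjusted p = 0.00135, and 0.378 with an estimated correlation). Thyroid hormone transport and metabolism had 2 of 5 higher (2 when adjusted over the list alone; 0.61, adjusted p = 0.014, and 0.469 with an estimated correlation). Of the response genes below the filter, thibz.L (4.01), crhbp.S (3.92), nfix.L (2.29), dio2.L (1.72) and thibz.S (1.22) were higher. Leaving out T3 48 h array 1 or 2 gave 4.77 and 3.36 for thibz.L and 5.001 and 3.32 for crhbp.S, and the call of dio2.L was lost without T3 6 h array 1 (adjusted p = 0.0526), T3 6 h array 3 (0.0507) or T3 48 h array 3 (0.0505). Extracellular matrix had 8 of 26 higher and 3 lower (8 and 3 when adjusted over the list alone; median 0.14, and 0.23 under quantile normalization, adjusted p = 0.00298, and 0.693 with an estimated correlation). bgn.L (2.12), the collagen col6a1.L (0.70), sparc.L (0.66) and nid2.L (0.61) were higher, and the list was at 0.209 without T3 48 h array 1. Growth signalling had 6 of 29 higher and 0 lower (6 and 0 when adjusted over the list alone; median 0.13, adjusted p = 0.00119, and 0.422 with an estimated correlation). Among them were the Notch target hes4.S (0.98), id2.L (0.96), the receptor fgfr1.L (0.93) and tgfbi.L (0.81). Lysosome and autophagy had 7 of 43 higher and 2 lower (7 and 2 when adjusted over the list alone; median 0.19, adjusted p = 0.00118, and 0.693 with an estimated correlation). Vascular endothelium had egfl7.S higher (0.55; list median 0.23, adjusted p = 0.0475, and 0.469 with an estimated correlation). This call was lost under quantile normalization (0.0749), under centring (0.0518) and without a filter (0.0831). It was also lost in 5 of the 9 fits that left out an array, to values from 0.0535 without vehicle array 2 to 0.132 without T3 48 h array 1, with 0.0746 and 0.0759 without T3 6 h arrays 2 and 3 and 0.0886 without T3 48 h array 2.

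The proteasome list, higher at 6 h, had 0 of 47 members higher and 10 lower at 48 h than at 6 h (16 lower when adjusted over the list alone; median -0.37, adjusted p = 5.62e-05, and 0.693 with an estimated correlation). Among them were psmd10.L (-1.14), the ubiquitin receptor adrm1.L (-1.06), psmb9.S (-0.81) and psmb2.L (-0.45). Of these only psmd10.L kept its call in all 9 fits without 1 array. The rise of the proteasome list at 6 h was read from the same T3 6 h arrays, which by itself favours a fall here. The same holds in reverse for extracellular matrix and growth signalling, lower at 6 h. Against vehicle at 48 h none of the 3 lists was called (adjusted p = 0.104, 0.788 and 0.773 in camera). Epidermis had 1 higher and 15 lower of 31 (1 and 18 when adjusted over the list alone; -0.66, adjusted p = 4.03e-05, and 0.422 with an estimated correlation), with lgals3.L at -1.89. Oxidative phosphorylation had 1 higher and 13 lower of 78 (1 and 16 when adjusted over the list alone; -0.24, and -0.16 under quantile normalization, adjusted p = 9.68e-05, and 0.693 with an estimated correlation), among them cox6a1.S (-0.56) and cox7c.S (-0.48). All 4 notochord and cartilage members that fell against vehicle were lower here as well (median -1.74), although the list was not called (adjusted p = 0.0735). Lists with larger adjusted p were ER stress and chaperones (0.104), myogenic regulators (0.135), pigment cells (0.271), leukocytes (0.285), corticosteroid axis (0.285), glycolysis (0.349) and nuclear receptor coregulators (0.373). Still larger were those of circadian clock (0.389), immediate early genes (0.407), cell cycle and DNA replication (0.725), ribosomal proteins (0.754), neural (0.761), liver, pancreas and gut (0.882), apoptosis (0.932) and erythroid (0.988). Further genes lower at 48 h than at 6 h were mcrip2.S (-2.44), the glutathione transferase gstp1.L (-2.43), hk1.L (-2.21) and tmem30b.L (-2.01). The muscle list had tnnc1.S (-0.43) and pdlim5.L (-0.59) lower among 50 (0 when adjusted over the list alone), with an adjusted p of 0.891. Neither gene kept its call in all 9 fits without 1 array. Leaving out T3 48 h array 1 gave 15 higher and 2 lower for lysosome and autophagy, 6 and 4 for extracellular matrix, 0 and 5 for the proteasome, 1 and 18 for oxidative phosphorylation, 1 and 16 for epidermis, and 7 and 0 for growth signalling. It gave 9 and 1 for matrix-degrading enzymes, 3 and 0 for T3 response genes, 2 and 0 for thyroid hormone transport and metabolism, and 0 and 0 for vascular endothelium. Without T3 6 h array 2 the counts were 0 and 11 for the proteasome, 1 and 12 for epidermis, 0 and 17 for oxidative phosphorylation, 9 and 3 for extracellular matrix, 6 and 2 for lysosome and autophagy, 0 and 4 for erythroid and 0 and 0 for vascular endothelium, and those of matrix-degrading enzymes, T3 response genes, thyroid hormone transport and metabolism, growth signalling, and notochord and cartilage were equal to those of all 9 arrays.

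Few calls were shared between 6 h and 48 h against vehicle. Of 18 and 892 probe sets, 3 were called in the same direction, sfrp2.S and tmem52.L lower and an unnamed probe set higher, and 3 in opposite directions. The unnamed probe set rose by log2 0.83 at 6 h and 2.81 at 48 h. Those with opposite directions were eef1aknmt.S (0.99 at 6 h and -0.50 at 48 h), lmbr1l.L (-0.82 and 0.58) and another unnamed probe set (1.01 and -0.78). The probe sets without a gene name, and both genes' values at 48 h, were chosen after the values were seen. An overlap of 3 compared with a mean of 0.02 and at most 1 in 100 simulations of unchanged groups that shared simulated vehicle arrays. The simulated groups had a mean of 0.08 and 0.15 calls, so they are no comparison for lists of 18 and 892. For independent lists of these sizes the overlap is 0.691 higher and 0.242 lower. The vehicle arrays, 3 in number, could not be split, so part of the excess may come from shared controls. Across the tested probe sets the fold changes correlated at r = 0.207, against 0.502 in the simulations, and their covariance was 0.0304 against a simulated 0.0190, a difference of 0.0113. Probe sets are not independent replicates. The signs were equal for 56.1% of probe sets, against 66.6% in the simulations. The simulated groups held no change, and change in only 1 comparison lowers both r and the share of equal signs. The simulated r and share are therefore no comparison for the measured ones. The overlap was 42 without T3 48 h array 1, from 99 and 1912 calls, and 140 with array weights, from 547 and 1979 calls. It was 0 without vehicle array 1 or 2, T3 6 h array 1 or 3, or T3 48 h array 2 or 3. It was also 0 under quantile normalization, without a filter and with the replicate number as a block. The size of the overlap therefore depended on the fit.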

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

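The test of a mixed pool and the splits of the arrays were fixed before their results were seen, and the tests of a wrong label, of compressed values, of the 6 h lists and of the oxidative phosphorylation list were chosen only after the result was seen. The bootstrap intervals below resampled genes or probe sets, not arrays. They do not measure the spread between pools and are too narrow where genes move together.

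T3 48 h array 1 lay nearer to the vehicle arrays than T3 48 h arrays 2 and 3 did. Over the 1912 probe sets called without it, its change had a slope of 0.510 on the mean change of the other 2 arrays, with 1693 in the same direction, whereas the highest slope of a T3 6 h array was 0.162, which argues against a mislabelled vehicle or T3 6 h pool. A mixture with RNA of tails that did not respond was predicted to give rises and falls the same share of the linear change. The median share was 0.295 for rises and 0.538 for falls, a difference of -0.243 (95% bootstrap interval over probe sets -0.276 to -0.213). This does not decide against a mixture. The probe sets were selected on arrays 2 and 3, which also set the change that array 1 was compared with, and no other array was tested in this way. A mixed pool therefore stays open. The SD of the log2 values of T3 48 h array 1, 1.96, lay within the 1.94 to 1.97 of the other 8 arrays, against compressed values. A weaker or slower response in that pool is a hypothesis these values may suggest, untested since no group of the design separates it. A scan day or batch of its own stays open, because none is given in the sources used here.

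At 6 h the proteasome list rose and the extracellular matrix and growth signalling lists fell (adjusted p = 0.693, 0.489 and 0.373 with an estimated correlation), with a mean shift of 0.27 over 102 members in the direction of their list. More blood in the T3 6 h tails would dilute muscle genes alike. The muscle median lay 0.32 (interval over genes 0.18 to 0.43) above that of both lists that fell. This argues against dilution for these lists, although the spread between pools was not measured. Quantile normalization and centring left all 3 lists called in camera at the preset correlation, with a largest adjusted p of 0.000432. Camera compares a list with the other genes, so a shift of a whole array could hardly end a call. The medians under these scalings were 0.18 and 0.16 for the proteasome, -0.34 and -0.35 for extracellular matrix and -0.30 and -0.31 for growth signalling. Neither scaling removed the shifts. Time in the container or handling cannot be told apart from T3 at 6 h, because no vehicle tails of 6 h are among these arrays. A share of -0.0921 of the shift was found at 48 h (interval -0.488 to 0.258), where T3 and vehicle tails spent equal time, so these values do not show that it persists. An early transient response to T3 is likewise open. So is chance movement of correlated genes, since no list was called with an estimated correlation.

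The oxidative phosphorylation list fell at 48 h (adjusted p = 0.693 with an estimated correlation; median -0.22, and -0.15 under quantile normalization). A smaller share of muscle RNA is argued against by the muscle median, which lay 0.24 (interval over genes 0.15 to 0.29) above that of the list. The spread of this difference between pools was not measured. Under quantile normalization and centring the list kept its call in camera at the preset correlation, with a largest adjusted p of 0.000992. Its median was -0.15 and -0.20 there, so its size depended on the scaling while its sign did not. A smaller share of epidermal RNA cannot be told apart from regulation within cells, since the share of epidermal members below 0 was 0.806 while the members differed among themselves by more than their errors (chi-square over degrees of freedom 10.5). A response to T3 within cells stays among the open explanations, untested. Chance movement of correlated genes is open too, since no list was called with an estimated correlation.

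With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real splits gave 18 probe sets at 6 h (highest other split 1), 892 at 48 h (highest other 1) and 1578 for T3 48 h against T3 6 h (highest other 2). Among the gene lists they gave 8 at 6 h (highest other 10), 10 at 48 h (highest other 12) and 10 for T3 48 h against T3 6 h (highest other 9). The overlap of 3 calls between 6 h and 48 h was reached in 1 of 100 regroupings of the 9 arrays, the real one, with 2 as the highest other. As 0 of the 99 others had 3 calls in both comparisons, this does not test an overlap of lists of 18 and 892, a limit set after the result was seen. The regroupings with the most calls, 586 and 668, put all 3 T3 48 h arrays in 1 group.

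T3 48 h against T3 6 h, which is also the difference between the effects at 48 h and at 6 h, was called in limma for 91 named probe sets and 10 lists. Those groups differ in time in the container as well as in T3. The values are log2 differences, 48 h minus 6 h. Of the 80 results that the rule named in this comparison, 55 kept their call in all 9 fits without 1 array. Those of hdac1.S, hdac2.S, id2.L, canx.L, psmb8.L and gpnmb.L were among the ones that did not. Among T3 response and hormone-handling genes the difference was 4.01 for thibz.L (4.77 without T3 48 h array 1 and 3.36 without array 2), 3.92 for crhbp.S (5.001 and 3.32), 2.29 for nfix.L, 1.72 for dio2.L, 1.46 for dio3.L, 1.30 for crym.S, 1.22 for thibz.S, 2.50 for mmp11.L and 4.54 for fap.L. Among matrix proteases, their inhibitor and matrix genes the difference was 4.20 for mmp13l.S, 2.26 for dpp4.S, 1.76 for timp2.L, 2.12 for bgn.L, 0.70 for col6a1.L, 0.66 for sparc.L, 0.61 for nid2.L and 0.81 for tgfbi.L. Among cartilage genes the difference was -1.67 for col9a1-b, -1.74 for cnmd.L, -1.83 for col2a1.S and -1.96 for col9a1.L (-2.60 without T3 48 h array 1). Among keratins and other epidermal genes the difference was 3.07 for krt78.6.L, -2.63 for krt12.4.L, -3.47 for krt12.4.S, -1.20 for krt12.5.S, -1.89 for lgals3.L and -0.93 for pkp3.S. Among lysosomal, autophagy and cell-death genes the difference was 2.25 for glb1.L, 2.10 for atg16l1.L, 1.09 for gabarapl1.S, -1.58 for sqstm1.L and 0.49 for bnip3.S. Among ER and chaperone genes the difference was 0.69 for pdia4.L, 0.61 for canx.L, 0.59 for calr.L and -0.76 for hspe1.L. Among proteasome genes the difference was -0.45 for psmb2.L, -0.78 for psmb8.L, -0.81 for psmb9.S, -1.06 for adrm1.L and -1.14 for psmd10.L. Among respiratory and sugar metabolism genes the difference was -0.32 for ndufa8.L, -0.47 for ndufs8.L, -0.48 for cox7c.S, -0.53 for ndufs4.S, -0.56 for cox6a1.S, -2.21 for hk1.L and -0.78 for slc2a4.L. Among neural genes the difference was 1.99 for gap43.S, -1.41 for stmn1.L, -1.07 for syt1.L and -0.95 for vamp2.L. Among muscle and myogenic genes the difference was 1.02 for myod1.S, -0.43 for tnnc1.S and -0.59 for pdlim5.L. Among coregulators and signalling genes the difference was 0.91 for ncoa3.S, 0.76 for ncor1.S, 0.44 for hdac2.S, 0.42 for hdac1.S, 0.98 for hes4.S, 0.96 for id2.L, 0.93 for fgfr1.L and 0.79 for klf6.L. Among genes of pigment, blood, vessel, liver, clock and corticosteroid lists the difference was -1.01 for rab27a.L, 0.66 for gpnmb.L, 1.24 for cxcr4.L, 0.55 for egfl7.S, 1.57 for arg1.L, -0.83 for arntl.L and 0.55 for tsc22d3.L. Among the other genes with the largest rises the difference was 5.55 for mamdc2.L, 4.18 for slc15a2.L, 3.95 for ambp.L (2.78 without T3 48 h array 1 and 4.96 without array 2), 3.34 for anxa1.3.S and 3.29 for anpep.L. Among the other genes with the largest falls the difference was -3.46 for thdl17.L, -3.12 for thdl18.S (-4.51 and -4.17 without T3 48 h array 1), -2.66 for fucolectin.S, -2.65 for otogl2.L, -2.44 for mcrip2.S, -2.43 for gstp1.L, -2.01 for tmem30b.L and -1.89 for atp12a.L. Among the other genes called at 6 h the difference was 1.40 for lmbr1l.L, -1.33 for gclm.L, -1.43 for ocm4.3.S, -1.49 for eef1aknmt.S, -1.09 for mrto4.L, -1.02 for lgals4.2.L, -0.59 for grina.L and -0.52 for arpp19.L.

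The adjusted p of the difference between 48 h and 6 h in camera was 8.83e-06 for matrix-degrading enzymes, 4.03e-05 for epidermis, 5.62e-05 for the proteasome, 9.68e-05 for oxidative phosphorylation, 0.00118 for lysosome and autophagy, 0.00119 for growth signalling, 0.00135 for T3 response genes, 0.00298 for extracellular matrix, 0.014 for thyroid hormone transport and metabolism and 0.0475 for vascular endothelium. With an estimated correlation the adjusted p in the same order was 0.378, 0.422, 0.693, 0.693, 0.693, 0.422, 0.378, 0.693, 0.469 and 0.469. Outside the main measurement, the 18 spike control probe sets averaged 4.09 ± 0.38 in vehicle, 4.45 ± 0.30 at 6 h and 4.58 ± 0.13 at 48 h (SD, n = 3, log2 over the array median). The T3 48 h arrays were 0.49 above vehicle (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give).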

How the results depend on the processing

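The filter as first written, centring for the gene lists, the filter at log2 6 for the gene lists and the list counts without T3 48 h array 1 or T3 6 h array 2 were chosen after the data had been seen. Probe sets called are given in the order T3 6 h, T3 48 h (both against vehicle), T3 48 h against T3 6 h, and overlap, against 18, 892, 1578 and 3. They were 2, 605, 1323 and 0 without a filter, 0, 16, 30 and 0 with the filter at log2 6, 6, 121, 247 and 1 with the filter as first written at log2 4, where fewer probe sets were tested, 1, 865, 1489 and 0 with quantile normalization, 547, 1979, 2677 and 140 with array weights (lowest weight 0.377, T3 48 h array 1), 0, 158, 569 and 0 at an adjusted p under 0.01, and 7, 270, 397 and 0 with at least a 2-fold change. With only the 2 groups compared in the fit the counts were 66, 494 and 1105. Beside the counts of 0 from limma at 6 h, 1270 of the 8123 probe sets had an unadjusted p under 0.05 without any of these changes. Leaving out 1 array at a time gave 0 to 99 at 6 h, 256 to 1912 at 48 h, 869 to 2093 between both and 0 to 42 for the overlap. The calls of T3 48 h against T3 6 h were 38.7% higher, and 47.5% with quantile normalization and 50.2% with centring. Centring, the variance models and leaving out probe sets that can match several transcripts kept each count within 1.5 times.

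The correlations between arrays gave no sign that the replicate numbers pair them. Of 9 same-number pairs 1 had a correlation of deviations over 0.1 (range -0.13 to 0.10). Only 1 array correlated best, in each of the other groups, with the array of its own number. With the replicate number as a block the counts were 0, 700, 1364 and 0.

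Of the 81 list tests 28 were called, and 0 with an estimated correlation, 14 with fry, 15 with the filter at log2 6, 16 with the filter as first written and 24 to 29 without 1 array. Of the 28, quantile normalization kept 26, centring 25, the replicate block 27, no filter 27 and fry 11 in the same direction. The calls lost under quantile normalization were ribosomal proteins at 48 h and vascular endothelium between 48 h and 6 h, those lost under centring were these and immediate early genes at 6 h, and that lost with the block or without a filter was vascular endothelium. Using the mean over the probe sets of a gene kept 28. Called lists that changed direction were ER stress and chaperones at 48 h with the filter at log2 6 (adjusted p = 0.854) and immediate early genes at 6 h with the filter as first written (0.841). A result of a named gene counted as kept if it was called in the same direction, or uncalled in both fits whatever its direction. Of the 205 results, 201 were kept with array weights, 197 with centring, 187 with quantile normalization, 203 with robust eBayes and 199 without the trend. With the replicate block 175 were kept, and 170 with only the groups compared. Without a filter 129 of 169 were kept, and without 1 array 1438 of 1845. None changed direction among the called. Apart from the smaller number of probe sets under the stricter filters, the cause was not tested. For want of detection calls, signal over background is unknown, which limits values below the array median.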

Other observations

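The genes of the next paragraphs fall outside the naming rule and were chosen after their values were seen, and the homeolog comparison and the test of NRF2 targets were chosen only after results were seen.

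At 48 h, some further single genes were lower than in vehicle. Except for the agr2 homeologs, whose gene is on the epidermis list tested above, they lay outside the lists. No list of them was tested. Uroplakins, proteins of the apical plaques of epithelial cells, were lower for upk1b.S (log2 -1.51 ± 0.25 SE, n = 3, adjusted p = 0.00746 in limma), upk3a.L (-1.25 ± 0.17), upk1b.L (-1.09 ± 0.30) and upk1a.S (-1.02 ± 0.25). The secreted disulfide isomerase family had ag1.L at -1.80, ag1.S at -1.61 and -1.44 for its probe sets, and agr2.S at -1.24, with agr2.L at -1.03 not called (adjusted p = 0.0673). The keratins krt62.L (-1.34 ± 0.20) and krt7.L (-1.31 ± 0.20), among the brighter probe sets at 7.72 and 7.39 in vehicle, were lower as well, whereas krt18.1.L (-0.66, adjusted p = 0.258) and krt18.1.S (-1.53, adjusted p = 0.0521) were not called. At 6 h the values of upk1b.S (-0.22), krt62.L (0.02) and krt7.L (0.23) were not called.

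Also at 48 h, pck1.L (log2 1.70 ± 0.37, adjusted p = 0.0200 in limma) and g6pc1.3.L (1.42 ± 0.22), enzymes of glucose synthesis, were higher, as was the glycine cleavage enzyme gldc.S (1.87 ± 0.39), whereas fbp1.L (0.18) was not called. The retinoic acid receptor rara.L (1.63 ± 0.23), the histone methyltransferase ezh2.L (1.36 ± 0.14) and the posterior homeobox gene hoxc12.L (1.05 ± 0.22) were higher. Further rises were in mfge8.S (2.01 ± 0.22), which marks dying cells for uptake by phagocytes, in both homeologs of the hyaluronidase hyal2, hyal2.L (1.44) and hyal2.S (0.91), and in the gelatinase mmp9.2.L (1.95 ± 0.17), whose vehicle mean of -1.14 lay below the array median. The transglutaminase tgm2.S rose by 2.37 ± 0.20 while the probe set of tgm2.L was at 0.01 (adjusted p = 0.984). The difference between homeologs was not tested.

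Among 572 pairs of homeologs with both members tested, 19 were called in the same direction at 48 h, 10 higher and 9 lower, against 3.35 for independent calls, 0 in opposite directions, and 86 with 1 member called. Across pairs the log2 changes correlated at r = 0.662 (Spearman's rho 0.61), and the highest r in 10000 shuffles was 0.161. Pairs of genes are not independent replicates, and probe sets that bind both homeologs would raise these values, which was not tested.

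The rises of gclm.L and sqstm1.L at 6 h led to the hypothesis that other targets of NRF2, a transcription factor of the oxidative stress response, may have risen with them. Without these genes, the 25 measured members of a list of NRF2 target genes had a median log2 change of 0.08 at 6 h, with 14 members positive and 0 called. The p of the list was 0.592 in camera with an estimated correlation and 0.353 with the preset one. The members went both ways, so the hypothesis stays open.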
